A study of Mus musculus with 24 samples.

How the data were processed

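RNA was measured in 24 libraries of 4T1-T mouse breast cancer cells that carried an shRNA against Asns (shAsns-1 or shAsns-2) or the control shRenilla. Per the labels, the cells had been isolated from primary tumors or lung metastases, selected in 6-thioguanine and grown in DMEM with non-essential amino acids. The 6 groups of site and hairpin hold 4 libraries each, with the letters A to D. Total RNA was prepared with Trizol and libraries with the NuGEN Ovation RNAseq V2 kit. The labels name Bowtie2, HTSeq and the build mm10 without versions. They do not state the annotation, the strand setting or any filter.

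The deposited values are raw counts per gene symbol, for 23478 symbols, and they were used without change. Total counts per library, in M, ran from 8.48 to 38 (median 28.7, lowest in tumor shAsns-2 A), and the 10 highest genes held 4.56 to 5.81% of them. No library duplicated another: the lowest chi-square per degree of freedom was 4.96 between libraries of a group and 5.95 over the 240 pairs from different groups. The labels do not say whether replicates are separate mice, cultures or preparations, so p-values measure the spread between these libraries, which could be partly technical. The biological coefficient of variation was 14.9%. Symbols were matched to GENCODE M21 for position, GC content and length (21909 of 23478 symbols, and 11901 of 12625 tested genes, 94.3%).

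Genes were tested with edgeR 4.0.16 in R 4.3.3, by a quasi-likelihood fit with robust dispersion over all 24 libraries, 1 mean per group, TMM scaling and the filterByExpr filter, which kept 12625 genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. Standard errors were the absolute log2 fold change over the square root of the F statistic. Levels are means and SD of CPM, and log2 CPM for components and lists used a prior count of 2. The planned comparisons were each Asns hairpin against shRenilla and the hairpins against each other at each site, lung against tumor within each hairpin, genes called alike with both hairpins, and the difference of the mean effect of both hairpins between sites.

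Gene lists were fixed beforehand: 20 lists of pathways and cell states and 9 of cell type markers. They were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with the correlation estimated and with fry. Adjustment was within a comparison and kind of list. Members were also adjusted over the list alone. Genes to be named were set by fixed rules: the target, top genes by fold change at a mean log2 CPM of at least 3, called members of lists, and 8 genes of epithelial-mesenchymal transition, of which Snai2 was too low to be tested. For lung against tumor in shRenilla, top genes also needed all 4 lung libraries beyond all 4 tumor libraries. For changes measured against the same controls, unchanged groups were simulated 100 times and the controls were divided 2 and 2 in 6 ways. Exact p-values came from the 35 splits of 4 against 4, which give 0.0286 at the lowest.

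The tests were checked on simulated counts with the depth and dispersion of these libraries. For tumor shAsns-1 against shRenilla edgeR recovered 47.8, 83.6 and 93.9% of genes changed 1.5-, 2- and 4-fold, with 11 false calls among 12425 unchanged genes. For tumor shAsns-2 the values were 38.8, 80.6 and 97%, for lung shAsns-2 58.2, 82.1 and 97%, and for the difference between sites 23.9, 77.6 and 86.4%. A simulated change in 1 list was called by camera with both correlations and by fry, with 0 of 19 unchanged lists. All genes of that list were raised at least 1.5-fold, and genes were drawn independently of each other. The check therefore says nothing on false calls from correlated genes or on weaker changes of a list.

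The alternatives were DESeq2 1.42.0, its size factors in edgeR, limma with library weights, no filter, only the compared groups in the fit, counts thinned to the smallest library, the replicate letter in the model, a 2-fold minimum, and leaving out each library in turn. These choices and the comparisons were fixed before the data were examined. Fits without lung shRenilla B and lung shAsns-2 D, fits with offsets for GC content and length, the difference between sites label by label, and limma, no filter, thinned counts and only the compared groups for single named genes were added afterwards. No library was left out of the main results. Figures were drawn with matplotlib.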

Results

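Asns, the gene for asparagine synthetase and the target of both Asns hairpins, moved in opposite directions with the 2 hairpins. In tumor-derived cells it averaged 82.8 ± 15.9 CPM (mean ± SD, n = 4 libraries per group throughout) with the control hairpin shRenilla and 36.8 ± 10.3 CPM with shAsns-2, so it fell (log2 fold change -1.18 ± 0.16 SE, adjusted p = 0.00122). That call ended narrowly with only the compared groups in the fit (adjusted p = 0.0502, lowest of all alternatives 2.85e-08). In the tumor libraries labelled shAsns-1 it rose to 170 ± 17.1 CPM (1.04 ± 0.16, adjusted p = 1.47e-05). In lung-derived cells it rose from 63.6 ± 7.89 CPM in shRenilla to 194 ± 18.2 CPM in the libraries labelled shAsns-1 (1.61 ± 0.16, adjusted p = 2.62e-06). With shAsns-2 in lung it averaged 44.6 ± 6.51 CPM, below shRenilla in 4 of 4 libraries, but was not called by edgeR (-0.51 ± 0.16, adjusted p = 0.405, exact p = 0.0286, the smallest that 4 against 4 can give). Limma with library weights called it (adjusted p = 0.0017), in a range of 0.0017 to 0.955 over all alternatives.

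The per-library plot of Asns showed no overlap between groups at either site. In tumor the libraries labelled shAsns-1 ranged from 152 to 185 CPM, shRenilla from 61.7 to 100 CPM and shAsns-2 from 26.2 to 48.3 CPM. In lung the ranges were 176 to 219, 53.1 to 70.2 and 35.8 to 51.3 CPM. Asns lies on chromosome 6 (7675169 to 7693254, minus strand, GRCm38). The rise runs against a knockdown, so for the libraries labelled shAsns-1 every direction below is a direction between labels, and none is read as an effect of lowering Asns. An exchange of the shAsns-1 and shRenilla labels at both sites is not excluded, and under it the libraries labelled shRenilla would carry an Asns hairpin. Comparisons with shRenilla are therefore comparisons between labels as well.

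Hprt, whose loss gives resistance to the 6-thioguanine used for selection, was called in no comparison of hairpins in the main edgeR fit. In lung it lay below every shRenilla library in 4 of 4 libraries labelled shAsns-1 (453 ± 31.2 against 626 ± 115 CPM, log2 fold change -0.47 ± 0.16, adjusted p = 0.277, exact p = 0.0286). Limma with library weights called it lower there (adjusted p = 0.0194, range over all alternatives 0.0194 to 0.7) and between the hairpins in lung (adjusted p = 0.00119, range 0.00119 to 1). In tumor libraries labelled shAsns-1 it was called lower than in shRenilla by limma (adjusted p = 0.012) and with GC content and length offsets (adjusted p = 0.00259, range 0.000782 to 0.349). With those offsets it was also lower than in tumor shAsns-2 (adjusted p = 0.0049, range 0.0019 to 0.841).

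**Figure D1:**
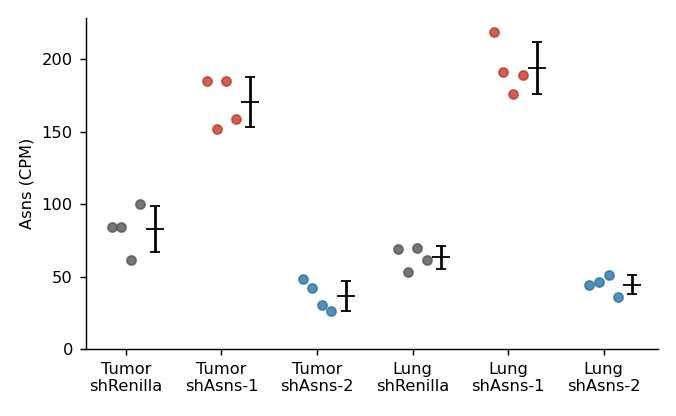
Asns in CPM for each of the 24 libraries, by site of isolation and hairpin label. The black mark and bar beside each group give the mean and SD of its 4 libraries.

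Tumor-derived libraries labelled shAsns-1 had lower levels of 39 of 54 epithelial genes than tumor shRenilla, and lay with the lung-derived libraries on the first principal component. Cdh1, which encodes the adhesion protein E-cadherin, fell from 226 to 36.4 CPM (log2 fold change -2.64 ± 0.18, adjusted p = 4.14e-11). Esrp1, an epithelial splicing regulator, fell from 41.3 to 3.5 CPM (-3.58 ± 0.47, adjusted p = 2.05e-06). Vim, the mesenchymal filament gene, rose (0.66 ± 0.12, adjusted p = 0.00012), as did the transcription factor genes Twist1 (1.07 ± 0.16, adjusted p = 1.75e-05) and Zeb2 (0.75 ± 0.15, adjusted p = 0.000263). Fn1, for fibronectin, fell (-0.90 ± 0.19, adjusted p = 0.00054), while Snai1 (adjusted p = 0.227) and Zeb1 (adjusted p = 0.854) were not called. The fixed mesenchymal list as a whole did not rise. Its mean log2 CPM over 53 genes was 2.39 to 2.54 in these libraries and 2.62 to 2.92 in tumor shRenilla. In all, 4278 of 12625 genes were called between these libraries and tumor shRenilla, 2041 higher and 2237 lower, of which 958 changed at least 2-fold. The balance turned to 2706 higher and 2472 lower with GC content and length offsets. On the first component, with 38.8% of variance, the 4 tumor libraries labelled shAsns-1 lay at -21.6 to -14.3. Lung libraries lay at -27 to -13.2, except lung shAsns-2 D at 0.199, and the other tumor libraries at 32.4 to 43.7. On the second component, with 12.2%, those 4 lay at 21.3 to 30.8, beyond every lung library (-29.2 to 9.85).

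**Figure D2:**
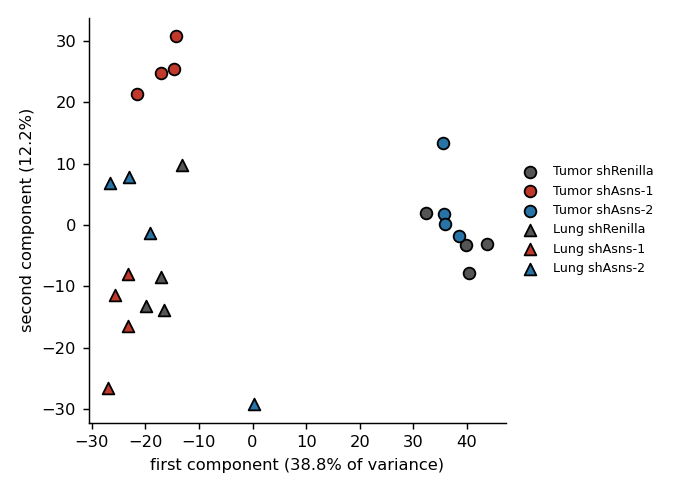
First and second principal components of the 24 libraries from log2 CPM of all tested genes. Circles are tumor-derived and triangles lung-derived libraries, colored by hairpin label.

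Of the fixed gene lists, the epithelial genes moved furthest in tumor libraries labelled shAsns-1: 1 rose, 39 fell and 14 of 54 were not called (median log2 fold change -1.45, camera adjusted p = 7.88e-21 and adjusted p = 0.00398 with an estimated correlation). Inflammatory cytokine and chemokine genes also moved down, with 6 higher and 20 lower of 34 (adjusted p = 5.94e-05, but adjusted p = 0.167 with an estimated correlation). Cxcl1, a neutrophil-attracting chemokine, fell from 332 to 82 CPM (-2.02 ± 0.14, adjusted p = 4.99e-11). Cholesterol and fatty acid synthesis had 1 higher and 15 lower of 31, with Cyp51 at -1.48 ± 0.19 and Sqle at -1.25 ± 0.15 (adjusted p = 1.55e-05, and adjusted p = 0.128 with an estimated correlation). The TGF-beta response had 2 higher and 11 lower of 25, among them Ctgf (-2.82 ± 0.28) and Itgb6 (-2.88 ± 0.21) (adjusted p = 0.00263, and adjusted p = 0.406 with an estimated correlation).

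Genes that load and fold new protein were lower as well. Of 20 cytosolic aminoacyl-tRNA synthetases 14 fell and 0 rose, for example Sars (-0.85 ± 0.18) and Tars (-0.65 ± 0.08) (adjusted p = 2.71e-06, and adjusted p = 0.167 with an estimated correlation). The unfolded protein response had 3 higher and 14 lower of 28, with the chaperone gene Hspa5 at 1560 against 3330 CPM (-1.10 ± 0.20) (adjusted p = 0.00213, and adjusted p = 0.406 with an estimated correlation). Amino acid transporters had 1 higher and 8 lower of 19, among them Slc3a2 (-1.08 ± 0.15) (adjusted p = 0.0325, adjusted p = 0.0568 without tumor shRenilla C, and adjusted p = 0.53 with an estimated correlation). NRF2 antioxidant targets went up, 17 higher and 4 lower of 30, with Gstm1 at 1.99 ± 0.29 and Hmox1 lower at -1.15 ± 0.26 (adjusted p = 0.00673, and adjusted p = 0.128 with an estimated correlation). Hypoxia and glycolysis genes had 11 higher and 4 lower of 37, with Bnip3 at 1.58 ± 0.26 (adjusted p = 0.0327, adjusted p = 0.0534 without tumor shRenilla D, and adjusted p = 0.406 with an estimated correlation). Targets of ATF4, the transcription factor of the amino acid response, went both ways (6 higher, 7 lower of 35), and camera did not call the list (adjusted p = 0.545). With the correlation estimated, the epithelial list was the 1 list of 20 still called, against 9 with the preset correlation and 13 by fry.

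Between tumor-derived shAsns-2 cells, where Asns was lower, and tumor shRenilla edgeR called few genes. As an exchange of the shAsns-1 and shRenilla labels is not excluded, the count does not measure the effect of lowering Asns. Beside Asns, the called genes included Car9, a hypoxia-responsive carbonic anhydrase, which rose from 13.5 to 34.4 CPM (log2 fold change 1.36 ± 0.22, adjusted p = 0.00759, but adjusted p = 0.154 with only the compared groups and 7.62e-06 at the lowest). The protease inhibitor genes Serpinb6b (-0.63 ± 0.12, adjusted p = 0.0408) and Serpinb9 (-0.61 ± 0.11, adjusted p = 0.0168) fell. They belong to a family of near copies, so reads of relatives are not excluded. Neither call was firm: with only the compared groups both ended (adjusted p = 0.298 and 0.22), that of Serpinb6b also ended with thinned counts (adjusted p = 0.115) and without any 1 of the 8 libraries other than tumor shRenilla C (adjusted p = 0.0521 to 0.202), and that of Serpinb9 without tumor shAsns-2 B or D or tumor shRenilla A, B or D (adjusted p = 0.0521 to 0.141). In all 8 genes were called, 5 higher and 3 lower, with 893 at an unadjusted p under 0.05. The count moved with single libraries: it was 5, 3 and 5 without tumor shAsns-2 A, B and D, and 4 without each of tumor shRenilla A, B and D. DESeq2 called 47 genes, limma with library weights 13 (5 higher and 8 lower), edgeR with GC content and length offsets 19, with only the compared groups 3, and without lung shRenilla B and lung shAsns-2 D 50. Without tumor shRenilla C 4 were higher and 5 lower.

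The amino acid response went up as a group in tumor shAsns-2. None of the 35 ATF4 targets was called by edgeR over all genes, where 893 genes had an unadjusted p under 0.05, DESeq2 called 47 genes in all and limma 13. Adjusted over the list alone 6 rose and 0 fell (median log2 fold change 0.25, camera adjusted p = 5.25e-06 and adjusted p = 0.0106 with an estimated correlation). Hypoxia and glycolysis genes moved the same way: 1 of 37 was called and 9 rose when adjusted over the list alone (median 0.15, adjusted p = 1.02e-06 and adjusted p = 0.04 with an estimated correlation). Cholesterol and fatty acid synthesis was higher too (median 0.21, adjusted p = 5.16e-06, but adjusted p = 0.0909 with an estimated correlation). In total camera called 9 of 20 lists with the preset correlation, 2 with the estimated correlation, and fry called 3.

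Few genes were called by edgeR in the same direction with both hairpins in tumor. Serpinb6b and Serpinb9 were lower with each, Serpinb9 by -1.39 ± 0.11 (adjusted p = 4.21e-10) in the libraries labelled shAsns-1. In all 5 genes were called in the same direction, and Asns was 1 of 2 called in opposite directions, while 575 had an unadjusted p under 0.05 with both and the same direction. DESeq2 gave 36 in place of 5, limma 11, GC content and length offsets 14, only the compared groups 3, and the fit without lung shRenilla B and lung shAsns-2 D 39. The count of 5 was 3 without each tumor library labelled shAsns-1, 2, 2, 9 and 2 without tumor shAsns-2 A to D, and 1, 1 and 2 without tumor shRenilla A, B and D. The changes of all genes correlated with r = 0.40, but both share the shRenilla libraries: 100 simulations without any change gave r = 0.47 (0.45 to 0.50). The covariance was 0.0549 against a simulated 0.0211, a difference of 0.0337. With the controls divided 2 and 2 so that no library was shared, r was 0.08 to 0.34 (mean 0.23).

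In the direct comparison of hairpins in tumor, libraries labelled shAsns-1 held 4.66-fold the Asns of shAsns-2 (log2 fold change 2.22 ± 0.17, adjusted p = 1.84e-10). They were also far less epithelial: 1 of the 54 epithelial genes was higher and 42 lower (adjusted p = 1.63e-28 and adjusted p = 0.000699 with an estimated correlation). Cholesterol and fatty acid synthesis had 1 higher and 23 lower of 31 (adjusted p = 3.1e-11 and adjusted p = 0.0131 with an estimated correlation). Altogether 3424 genes were called, 1528 higher and 1896 lower, between 2 labels against the same gene. With GC content and length offsets that balance turned to 2266 higher and 2025 lower.

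In lung-derived cells, the genes called between the libraries labelled shAsns-1 and shRenilla included Asns and several epithelial genes. The tight junction gene Ocln fell from 6.44 to 2.34 CPM (log2 fold change -1.47 ± 0.19, adjusted p = 0.000259). The desmosome gene Dsg2 fell from 23.5 to 11.3 CPM (-1.06 ± 0.16, adjusted p = 0.00128), and the keratin gene Krt7 from 11.0 to 4.61 CPM (-1.27 ± 0.25, adjusted p = 0.0238). The call of Krt7 ended without any 1 of lung shAsns-1 A, C and D or lung shRenilla A, C and D (adjusted p = 0.0649 to 0.137), with no filter (adjusted p = 0.131) and with thinned counts (adjusted p = 0.0639). With only the compared groups in the fit none of these 3 was called (Ocln and Dsg2 adjusted p = 0.102, Krt7 adjusted p = 0.199), and their lowest values over all alternatives were 6.19e-10, 1.13e-07 and 0.000151. EdgeR did not call Cdh1 (-0.71 ± 0.18, adjusted p = 0.125), while DESeq2 (adjusted p = 0.0251), limma with library weights (adjusted p = 0.0185) and edgeR with GC content and length offsets (adjusted p = 0.0448) did, over a range of 0.0141 to 0.41 in all alternatives. Of 54 epithelial genes 7 fell and 0 rose, or 13 and 0 when adjusted over the list alone (median -0.28, adjusted p = 1.97e-10, but adjusted p = 0.085 with an estimated correlation). Mesenchymal genes had 11 higher and 0 lower of 53 when adjusted over the list alone (median 0.30, adjusted p = 2.44e-05, but adjusted p = 0.617 with an estimated correlation and adjusted p = 0.259 by fry). Lung shAsns-1 D stood apart in this list, with a mean log2 CPM of 4.01 against 3.14 to 3.46 in the other 3 libraries and 2.84 to 3.19 in lung shRenilla, and without it the list's adjusted p was 0.0167. Fibroblast markers lay the same way, with a mean log2 CPM of 2.33 to 3.79 against 1.76 to 2.29 in lung shRenilla, and so did the sum of Col1a1, Col1a2 and Col3a1 (1.33 to 19.1 against 0.58 to 1.75 CPM). None of the 9 fibroblast markers was called over all genes and 4 were higher when adjusted over the list alone (adjusted p = 0.181, 0.00215 without lung shAsns-1 B, 0.039 without lung shRenilla B and 0.412 without lung shAsns-1 D). In all 26 genes were called, 9 higher and 17 lower. DESeq2 called 72, limma 843 (450 higher and 393 lower), edgeR with GC content and length offsets 40, with thinned counts 15, and with only the compared groups 1. The count was 13 without lung shAsns-1 D, 12 without lung shRenilla A and 16 without lung shRenilla B.

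With shAsns-2 in lung no gene passed edgeR's threshold, Asns included. That is 0 of 12625 genes, with 1068 at an unadjusted p under 0.05, 2 called by DESeq2 and 1582 by limma with library weights. Without lung shAsns-2 D edgeR called 7. In simulated data of this design and depth, 82.1% of genes changed 2-fold were recovered in this comparison. Those data held many planted changes and no far libraries such as lung shRenilla B and lung shAsns-2 D. The share recovered could therefore be lower in the real libraries. Camera called 5 of 20 lists with the preset correlation, and none with the estimated correlation or by fry. The inflammatory list was lower, 0 genes rising and 8 falling when adjusted over the list alone (median -0.30, adjusted p = 8.05e-08, but adjusted p = 0.141 with an estimated correlation). The unfolded protein response was lower too (median -0.24, adjusted p = 8.05e-08, but adjusted p = 0.289 with an estimated correlation). ATF4 targets were higher (median 0.17, adjusted p = 0.00701, but adjusted p = 0.141 with an estimated correlation).

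Both hairpins together called 0 genes in lung by edgeR, with 463 at an unadjusted p under 0.05 in both and the same direction, 1 by DESeq2 and 202 by limma with library weights. Without lung shAsns-2 D edgeR called 1. The changes correlated with r = 0.58 with shared controls, against 0.50 in simulations without change (covariance 0.0379 against 0.0211, a difference of 0.0168). The simulated controls held no far library such as lung shRenilla B, which enters both changes. The difference is therefore not read as an effect shared by the hairpins. With the controls divided 2 and 2, r was 0.03 to 0.19 (mean 0.10).

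Between the hairpins in lung, libraries labelled shAsns-1 held 4.35-fold the Asns of shAsns-2 (log2 fold change 2.12 ± 0.16, adjusted p = 9.35e-09). The epithelial genes Epcam (-0.94 ± 0.15, adjusted p = 0.00424, but adjusted p = 0.097 with only the compared groups and 8.25e-06 at the lowest) and Dsg2 (-0.89 ± 0.16, adjusted p = 0.00876) were lower, and so was Macc1, which regulates invasive growth (-1.32 ± 0.17, adjusted p = 0.000117). Epithelial genes had 0 higher and 6 lower of 54 (adjusted p = 6.86e-19 and adjusted p = 0.00655 with an estimated correlation). The inflammatory list was higher, with 12 of 34 genes up when adjusted over the list alone (adjusted p = 6.45e-14 and adjusted p = 0.0109 with an estimated correlation). ATF4 targets were lower (median -0.17, adjusted p = 0.000433 and adjusted p = 0.0268 with an estimated correlation), although 2 members were called in each direction. In all 33 genes were called, 18 higher and 15 lower. DESeq2 called 63, limma 1921, edgeR with GC content and length offsets 61 (28 higher and 33 lower), with thinned counts 10 (3 and 7), with only the compared groups 6 (1 and 5), and without lung shRenilla B and lung shAsns-2 D 180. In the fit of the compared groups another split of the same 8 libraries called 248, so chance was not excluded for this count. The count was 19, 65 and 6 without lung shAsns-1 A, B and D, and 16, 7, 11 and 84 without lung shAsns-2 A, B, C and D.

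**Figure D3:**
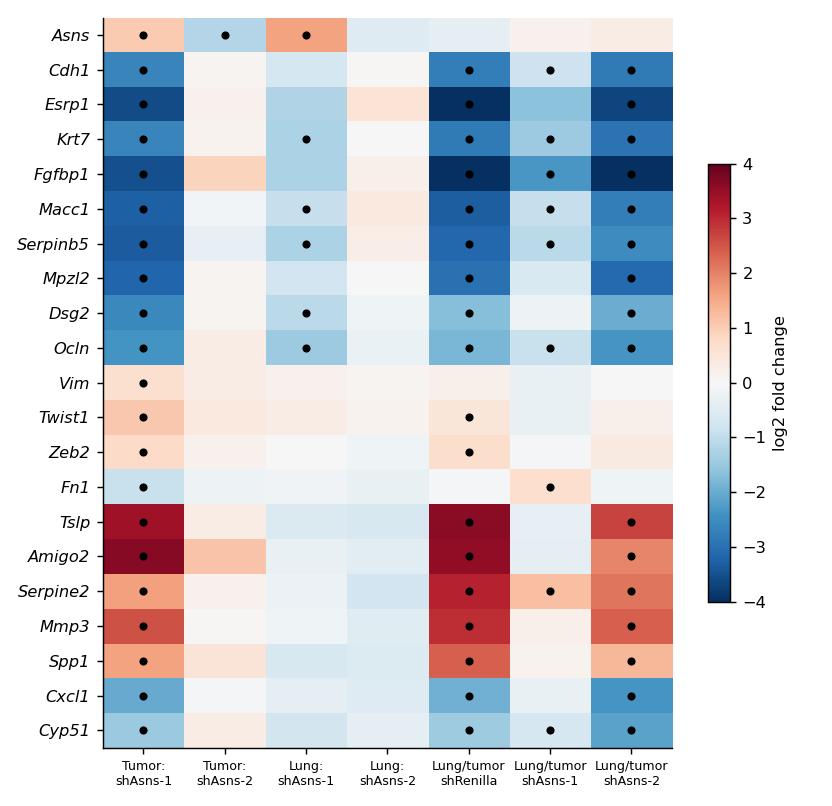
Log2 fold changes of genes chosen for display. The first 4 columns compare each hairpin label with shRenilla at its site, and the last 3 compare lung with tumor within a label. Black dots mark adjusted p under 0.05. Fill is limited at 4 in either direction.

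In the libraries labelled shRenilla, cells isolated from lung metastases differed in many genes from cells of the primary tumor. The cytokine gene Tslp rose from 46 to 567 CPM (log2 fold change 3.62 ± 0.20, adjusted p = 1.62e-12), the matrix protease gene Mmp3 from 87.1 to 668 CPM (2.94 ± 0.23, adjusted p = 3.5e-10) and the secreted phosphoprotein gene Spp1 from 1070 to 5620 CPM (2.39 ± 0.22, adjusted p = 4.23e-09). Serpine2, a protease inhibitor gene, rose as well (3.09 ± 0.26, adjusted p = 1.53e-09), as did Amigo2 (3.55 ± 0.24, adjusted p = 2.92e-11). Cdh1 fell from 226 to 33.3 CPM (-2.76 ± 0.19, adjusted p = 2.61e-11), Fgfbp1, which carries fibroblast growth factors, from 76.8 to 3.16 CPM (-4.60 ± 0.27, adjusted p = 2.66e-12), and Macc1 from 100 to 10.2 CPM (-3.29 ± 0.17, adjusted p = 3.62e-13). In all 4 lung libraries Tslp, Mmp3, Spp1, Serpine2 and Amigo2 lay above, and Fgfbp1 and Macc1 below, all 4 tumor libraries. That separation was a condition for naming them, so it is no added evidence. Twist1 (0.47 ± 0.16, adjusted p = 0.0409) and Zeb2 (0.70 ± 0.15, adjusted p = 0.000908) rose, but the call of Twist1 ended without any 1 of the 8 libraries other than tumor shRenilla C (adjusted p = 0.0546 to 0.146) and with only the compared groups (adjusted p = 0.0559). Vim (adjusted p = 0.261) and Fn1 (adjusted p = 0.771) were not called.

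In shRenilla 2749 genes were called between lung and tumor, 1509 higher and 1240 lower in lung. With GC content and length offsets that balance turned to 1769 higher and 1847 lower. Of 54 epithelial genes 1 rose and 36 fell (median -1.24, adjusted p = 9.96e-24 and adjusted p = 0.00199 with an estimated correlation). Cholesterol and fatty acid synthesis had 1 higher and 21 lower of 31, with Cyp51 at -1.42 ± 0.19 (median -0.63, adjusted p = 1.23e-10 and adjusted p = 0.0167 with an estimated correlation). Inflammatory genes went both ways, with Spp1 among 7 higher and Cxcl1 among 14 lower of 34. Camera called 8 of 20 lists with the preset correlation and these 2 with the estimated one, and fry called 7. Leukocyte markers moved with the site too, 5 higher and 1 lower of 7 tested (adjusted p = 0.0483, but adjusted p = 0.259 with an estimated correlation), a call that ended without any 1 of tumor shRenilla B, C and D or lung shRenilla B and C (adjusted p = 0.0502 to 0.0932). The sum over all 16 markers did not rise (163 CPM in tumor and 148 CPM in lung). Lcp1, its highest gene, went from 135 to 95.1 CPM.

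The shAsns-2 cells showed a similar difference between sites, in libraries that share none with the shRenilla comparison. Tslp rose (2.70 ± 0.20, adjusted p = 1.35e-10), Mmp3 rose (2.40 ± 0.22, adjusted p = 1.25e-08), and Cdh1 (-2.83 ± 0.19, adjusted p = 2.18e-11) and Fgfbp1 (-5.26 ± 0.27, adjusted p = 7.35e-13) fell. Of 2642 called genes 1270 were higher and 1372 lower in lung, and 1131 were higher and 1114 lower with no filter. With shRenilla, 909 were higher in both (152 expected by chance) and 817 lower in both (135 expected), with 0 opposite, and the changes of all genes correlated with r = 0.83. Epithelial genes had 0 higher and 37 lower of 54 (median -1.33, adjusted p = 2.01e-28 and adjusted p = 0.000712 with an estimated correlation). Cholesterol and fatty acid synthesis had 1 higher and 24 lower of 31 (median -0.93, adjusted p = 7.75e-18 and adjusted p = 0.00134 with an estimated correlation). NRF2 antioxidant targets had 13 higher and 2 lower of 30 (median 0.33, adjusted p = 0.00106 and adjusted p = 0.0428 with an estimated correlation). The count was 3977 without lung shAsns-2 D, 1650 with only the compared groups, 5064 with limma and 4926 without lung shRenilla B and lung shAsns-2 D.

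In the libraries labelled shAsns-1 the sites differed in another way. Cdh1 fell further, from 36.4 to 20.3 CPM (-0.84 ± 0.18, adjusted p = 0.00448), and Fgfbp1 (-2.33 ± 0.29, adjusted p = 2.25e-05) and Krt7 (-1.46 ± 0.25, adjusted p = 0.000642) fell. Tslp (-0.33 ± 0.18, adjusted p = 0.255) and Mmp3 (0.22 ± 0.21, adjusted p = 0.55), already high in tumor, were not called by edgeR, while limma called Tslp (adjusted p = 0.0267, range over all alternatives 0.0267 to 0.545). Mesenchymal genes had 26 higher and 0 lower of 53 in lung (median 0.73, adjusted p = 2.38e-12, but adjusted p = 0.23 with an estimated correlation). The tumor libraries labelled shAsns-1 were low in this list to begin with (mean log2 CPM 2.39 to 2.54, against 2.62 to 2.92 in tumor shRenilla). Part of this rise started near the floor and rested on 1 library: Col1a1, Col1a2 and Col3a1 summed to 19.1 CPM in lung shAsns-1 D, 1.33 to 4.15 CPM in the other 3 lung libraries and 0.179 to 1.4 CPM in tumor. Without lung shAsns-1 D the list was still called with the preset correlation (adjusted p = 1.53e-11). Of 54 epithelial genes 2 rose and 10 fell (median -0.14, adjusted p = 0.00338, but adjusted p = 0.412 with an estimated correlation). In all 1079 genes were called, 758 higher and 321 lower. That balance depended on the fit: there were 707 higher and 1111 lower with GC content and length offsets, and 1837 and 1846 with only the compared groups. With shRenilla 228 were higher in both (90.6 expected), 68 lower in both (31.5 expected) and 88 opposite (r = 0.26). The rank correlation over all genes was only 0.08, against 0.75 between shRenilla and shAsns-2. The count was 543, 532 and 663 without tumor shAsns-1 A, B and D, and 711, 707 and 412 without lung shAsns-1 A, C and D.

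Tumor libraries labelled shAsns-1 thus carried much of the lung pattern. Their changes against tumor shRenilla matched the lung against tumor changes of shAsns-2, which share no library with them: 764 genes were higher in both (205 expected), 924 lower in both (243 expected) and 21 opposite, with r = 0.68. Against tumor shAsns-2, they matched the lung against tumor changes of shRenilla in 821 genes higher (183 expected) and 845 lower (186 expected), with 7 opposite and r = 0.72.

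**Figure D4:**
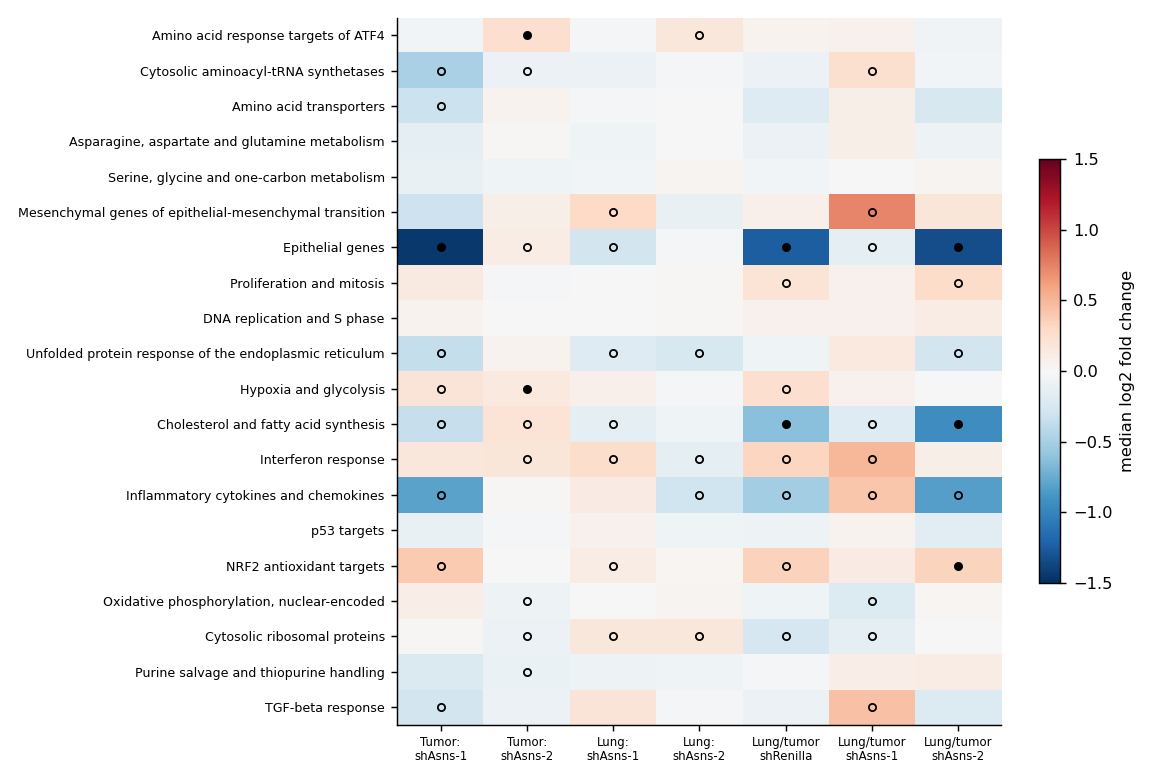
Median log2 fold change of the 20 fixed gene lists in the comparisons of each hairpin label with shRenilla and of lung with tumor. Filled dots mark lists called by camera with the preset and the estimated correlation, open dots those called with the preset correlation alone.

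The mean effect of the 2 Asns labels also differed between sites. Krt14, a basal keratin gene, had a higher change in lung than in tumor (difference 1.80 ± 0.21, adjusted p = 1.7e-05), as had Cdh1 (0.93 ± 0.22, adjusted p = 0.0163). Tslp (-2.44 ± 0.23, adjusted p = 7e-07) and Amigo2 (-2.77 ± 0.28, adjusted p = 1.24e-06) had a lower change in lung. In all 317 genes differed, 122 with a higher and 195 with a lower change in lung, and 172 without tumor shRenilla B. Epithelial genes had 10 with a higher and 1 with a lower change, or 22 and 1 when adjusted over the list alone (median 0.43, adjusted p = 4.36e-08, but adjusted p = 0.202 with an estimated correlation). Asns itself was not called (0.62 ± 0.19, adjusted p = 0.0943), although it was without tumor shAsns-2 A (adjusted p = 0.049) or tumor shRenilla C (adjusted p = 0.0401) and with limma (adjusted p = 0.0118, range over all alternatives 0.0118 to 0.208). This contrast averages 2 labels with which Asns moved in opposite directions, so it does not measure an effect of lowering Asns. Taken label by label, a comparison added after the Asns levels were seen, the difference called 1797 genes for the libraries labelled shAsns-1. For shAsns-2 edgeR called 0, with 599 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma with library weights, and edgeR called 1 without lung shRenilla B. Of the 20 lists camera called 8 in that shAsns-2 difference with the preset correlation, and none with the estimated correlation or by fry.

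Summed over 16 leukocyte markers, the group means lay between 140 and 181 CPM, with Lcp1 the highest gene in each group, and the median marker gene stayed at or below 0.18 CPM. Lcp1 made 135 of 163 CPM in tumor shRenilla and 97.9 of 140 CPM in tumor libraries labelled shAsns-1, so the sum can hide changes of other markers. Between these groups camera called 0 of the 9 marker lists with either correlation and fry called 1. The 19 fibroblast markers summed to 160 CPM in tumor libraries labelled shAsns-1 and 372 CPM in tumor shRenilla, with Fbln2 alone at 77.4 and 264 CPM. In libraries labelled shAsns-1, 5 of 9 tested fibroblast markers were higher in lung (adjusted p = 0.000426, but adjusted p = 0.115 with an estimated correlation). Of these 9 markers 3 are also in the mesenchymal list. There 2 of 5 tested macrophage markers were higher as well (adjusted p = 0.00468, but adjusted p = 0.115 with an estimated correlation), and fry called 5 of the 9 marker lists. Between lung and tumor in shRenilla camera called 1 of the 9 marker lists with the preset correlation and 0 with the estimated correlation, and fry called 4. The macrophage markers summed to 35.3 CPM in lung and 26 CPM in tumor, and the neutrophil markers to 6.97 and 3.96 CPM. Between lung and tumor in shAsns-2 camera called 0 with either correlation and fry called 4, with macrophage sums of 30.6 and 26.3 CPM and neutrophil sums of 6.44 and 3.62 CPM. Between the hairpins in lung, camera called 4 of the 9 marker lists with the preset correlation, 0 with the estimated correlation, and fry called 3. There the neutrophil markers summed to 11 CPM in libraries labelled shAsns-1 and 6.44 CPM in shAsns-2, of which S100a8, also in the inflammatory list, made 9.03 and 4.76 CPM.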

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

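The tests of misplaced libraries, of scaling and of exchanged labels for Asns, the collagen test, the label-by-label difference between sites, and the fits with GC content and length offsets or without lung shRenilla B and lung shAsns-2 D were chosen after the results were seen. The readings of the tests of a lung origin and of the fall of Asns were also revised after their values were seen, from in favor and against to open.

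Asns was higher, not lower, in the libraries labelled shAsns-1 at both sites. A few misplaced libraries are excluded, since 8 of 8 lay above every shRenilla library of their site, and so is the choice of scaling, since the lowest log2 difference under 3 scalings was 1.05. A general amino acid response is argued against by the other ATF4 targets, whose median log2 fold change was -0.03 at the site where it was higher. An exchange of the shAsns-1 and shRenilla labels at both sites and an off-target effect of the hairpin were not told apart. The lowest library labelled shAsns-1 held at least 1.52-fold the Asns of any other library of its site. That value restates the rise, so it cannot decide between them. Under an exchange, the 2 groups of each site with an Asns hairpin would be those labelled shRenilla and shAsns-2.

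The tumor libraries labelled shAsns-1 lay with the lung libraries on the first principal component, but apart from them on the second (21.3 to 30.8 against -29.2 to 9.85). Depth is excluded as the main source of the called genes, since thinning all libraries to the smallest total gave 3397 called genes against 4278, 3217 of them shared. The components were not recomputed on thinned counts. Tumor shAsns-2 A and B, with the smallest and largest totals (8.48 and 38 M counts), lay at 35.7 and 35.5 on the first component. Those values argue against depth for the position. A lung origin of these libraries cannot be told apart from a change in the tumor cells. Their lung against tumor changes correlated with those of shAsns-2 at 0.25, below the highest of the 34 other splits (0.32), as a lung origin predicts, but the sites still differed in 3683 genes against at most 24 in another split. The fall of Asns stays open too: shAsns-2 changes followed those of the libraries labelled shAsns-1 with a slope of 0.18 at most, under the limit of 0.25 set beforehand, but that limit was wrong because it took Asns to be lower in both, and an exchange of labels would put the control in the wrong group.

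Lung shRenilla B and lung shAsns-2 D lay far from their group mates, with root mean square log2 deviations of 0.55 and 0.419. GC content and length are excluded as the whole cause: removing their trend left 0.436 and 0.399, against 0.31 for the highest of the 22 other libraries. In lung shRenilla B they carried 31.9% of the variance of its log2 differences from the mean of all libraries. That measure also holds differences of site and hairpin. RNA of fibroblasts in lung shAsns-2 D is argued against as the cause by the sum of Col1a1, Col1a2 and Col3a1, at 1.23 CPM. That sum was still the highest of its group (others 0.478 to 0.765 CPM), as were the mean log2 CPM of fibroblast markers (2.42, others 1.67 to 1.85) and of mesenchymal genes (3.41, others 2.68 to 2.82). RNA quality stays open: among genes looked up after the result was seen, Hist1h4d (-4.94) and Rn45s (-2.76) were lower on the log2 scale than in the group mates in lung shRenilla B, and Malat1 (1.78) was higher in lung shAsns-2 D.

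Among 54 group values tested for 1 far library 7 stood out, where chance gives about 1 in 20. Beside those deviations they were the total of lung shAsns-1 C (35.5 M counts, others 24.8 to 25.8), the number of genes with counts in lung shAsns-2 D (16603, others 15601 to 15758), the first component of tumor shAsns-2 D (38.5, others 35.5 to 35.9), the mean log2 CPM of epithelial genes in tumor shRenilla D (3.52, others 3.83 to 3.88) and that of mesenchymal genes in tumor shAsns-2 D (3.02, others 2.70 to 2.75). Rn45s, the ribosomal RNA precursor, held 0.0277 to 0.0635% of counts in the tumor libraries labelled shAsns-1, 0.129 to 0.227% in tumor shRenilla and 0.0876 to 0.159% in tumor shAsns-2. A part of RNA make-up in the differences of those tumor libraries was not tested. Of 222 combinations of a printed gene and a group, 18 (8.11%) had a far library.

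The effect of the Asns labels differed between lung and tumor in 317 genes, among them Krt14 (adjusted p = 1.7e-05), Cdh1 (adjusted p = 0.0163), Tslp (adjusted p = 7e-07) and Amigo2 (adjusted p = 1.24e-06), and in the epithelial list (adjusted p = 4.36e-08, but adjusted p = 0.202 with an estimated correlation). For the libraries labelled shAsns-1 alone the difference took in 1797 genes, the epithelial list (adjusted p = 2.04e-14 and adjusted p = 0.0232 with an estimated correlation) and the inflammatory list (adjusted p = 1.33e-06, but adjusted p = 0.121 with an estimated correlation).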

How the results depend on the processing

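The fits without lung shRenilla B and lung shAsns-2 D, those with GC content and length offsets, with or without the replicate block, the label-by-label difference between sites, and limma, no filter, thinned counts and only the compared groups for single genes were chosen after the data were seen. The cause of a changed count was not tested unless stated.

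Reversals were scored for printed genes and lists only, and none of those with a call reversed. Among genes not called, Hprt changed sign in lung shAsns-2 against shRenilla with limma (adjusted p = 0.363), without lung shRenilla B and lung shAsns-2 D (adjusted p = 0.821) and leaving out either (adjusted p = 0.992 and 0.949, range 0.749 to 0.992 leaving out 1 library), and in tumor shAsns-2 without tumor shAsns-2 D (adjusted p = 1, range 0.662 to 1). Zeb1 did in tumor libraries labelled shAsns-1 without tumor shAsns-1 C (adjusted p = 0.655) or tumor shRenilla D (adjusted p = 0.965, range 0.641 to 0.965).

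The balance of directions turned in some counts. With GC content and length offsets lung against tumor in the libraries labelled shAsns-1 went from 758 higher and 321 lower to 707 and 1111, lung against tumor in shRenilla from 1509 and 1240 to 1769 and 1847, tumor libraries labelled shAsns-1 against shRenilla from 2041 and 2237 to 2706 and 2472, the hairpins in tumor from 1528 and 1896 to 2266 and 2025, and the hairpins in lung from 18 and 15 to 28 and 33. Those in lung also turned with no filter (10 and 12), thinned counts (3 and 7), only the compared groups (1 and 5), and without lung shAsns-1 D (1 and 5) or lung shAsns-2 A (4 and 12), B (2 and 5) or C (3 and 8). Lung libraries labelled shAsns-1 against shRenilla (9 and 17) turned with limma (450 and 393) and with only the compared groups (1 and 0), and tumor shAsns-2 (5 and 3) with limma (5 and 8) and without tumor shRenilla C (4 and 5). Lung against tumor in shAsns-2 (1270 and 1372) turned with no filter (1131 and 1114), a 2-fold minimum (295 and 292) and without tumor shAsns-2 A (1290 and 1231) or lung shAsns-2 B (975 and 919), and was even without lung shAsns-2 A (891 and 891). In the libraries labelled shAsns-1 it also turned with only the compared groups (1837 and 1846). The level of Asns kept its direction and size in all 60 settings. Of 1335 settings of printed genes 41 lost and 17 gained a call, 9 of the losses with only the compared groups and 7 of the gains with limma, and of 578 settings of gene lists 38 lost one, 24 of them with the estimated correlation and 5 with fry, and 2 gained one. The count of tumor libraries labelled shAsns-1 against shRenilla moved by over 1.5 times only with a 2-fold minimum (958), as did that between the hairpins in tumor (733).

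For tumor shAsns-2 against shRenilla (8 genes) DESeq2 gave 47, limma with library weights 13, only the compared groups 3, GC content and length offsets 19, and the fit without lung shRenilla B and lung shAsns-2 D 50. Leaving out 1 library gave 3 to 12. Genes alike with both hairpins in tumor (5) were 36 with DESeq2, 11 with limma, 3 with a 2-fold minimum or only the compared groups, 14 with GC content and length offsets, 39 without those 2 libraries, and 1 to 9 leaving out 1 library.

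Replicate letters need not pair samples: over 60 pairs of libraries with the same letter the deviations from group means correlated at 0.007 on average (-0.415 to 0.465). With the replicate block tumor shAsns-2 called 5 genes, without Serpinb6b (adjusted p = 0.0887) and Serpinb9 (adjusted p = 0.0525), and both hairpins in tumor 2. Twist1 between lung and tumor in shRenilla lost its call with it (adjusted p = 0.0503) and without lung shRenilla B and lung shAsns-2 D (adjusted p = 0.0645), in a range of 0.00212 to 0.146 over all alternatives. Leukocyte markers between lung and tumor in shRenilla lost theirs with it too (adjusted p = 0.0504) and without those 2 libraries (adjusted p = 0.065), in a range of 3.73e-05 to 0.259. Other counts moved by less than 1.5 times with the replicate block. Joined to the GC content and length offsets, the replicate block gave 17 for tumor shAsns-2, 11 for both hairpins in tumor, 50 for lung libraries labelled shAsns-1, 65 between the hairpins in lung, 1917 for lung against tumor in the libraries labelled shAsns-1, and 585 for the difference between sites.

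For lung libraries labelled shAsns-1 against shRenilla (26) DESeq2 gave 72, limma 843, thinned counts 15, a 2-fold minimum 11, only the compared groups 1, GC content and length offsets 40, and leaving out 1 library 12 to 29. For lung shAsns-2 (0) DESeq2 gave 2, limma 1582, GC content and length offsets 1, the fit without the 2 far libraries 4, and leaving out 1 library 0 to 7, with 7 without lung shAsns-2 D. For both hairpins in lung (0) DESeq2 gave 1, limma 202, and leaving out 1 library 0 to 1. Between the hairpins in lung (33) DESeq2 gave 63, limma 1921, thinned counts 10, a 2-fold minimum 20, only the compared groups 6, GC content and length offsets 61, the fit without the 2 far libraries 180, and leaving out 1 library 6 (lung shAsns-1 D) to 84 (lung shAsns-2 D).

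Lung against tumor in shRenilla (2749) moved to 4622 with limma and 735 with a 2-fold minimum. In shAsns-2 (2642) limma gave 5064, a 2-fold minimum 587, only the compared groups 1650, the fit without the 2 far libraries 4926, and leaving out 1 library 1782 to 3977. In the libraries labelled shAsns-1 (1079) limma gave 4138, thinned counts 695, a 2-fold minimum 260, only the compared groups 3683, the fit without the 2 far libraries 3015, GC content and length offsets 1818, and leaving out 1 library 412 to 794. The difference between sites (317) was 488 with DESeq2, 499 with limma, 176 with thinned counts, 149 with a 2-fold minimum, 547 with GC content and length offsets, and 172 to 353 leaving out 1 library.

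The correlation of the hairpins with shared controls fell when the controls were divided: in tumor from 0.40 to 0.20, 0.15, 0.34, 0.29, 0.32 and 0.08, and in lung from 0.58 to 0.03, 0.05, 0.19, 0.13, 0.12 and 0.09.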

Other observations

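Some differences between sites were not described above. In the libraries labelled shAsns-1 the lung-derived cells also had more interferon response (11 higher, 0 lower of 45 genes, adjusted p = 1.37e-06, but adjusted p = 0.352 with an estimated correlation). Lung shAsns-1 D stood apart, with a mean log2 CPM of 3.79 over the list against 2.89 to 2.98 in the other 3 lung libraries and 2.49 to 2.73 in tumor, and without it the adjusted p was 0.000934. They also had more TGF-beta response (12 higher, 0 lower of 25, adjusted p = 0.00024, but adjusted p = 0.412 with an estimated correlation). Tumor libraries of this label were already low in this list (mean log2 CPM 4.58 to 4.73, against 5.02 to 5.38 in tumor shRenilla). Lung libraries labelled shAsns-1 lay at 5.01 to 5.27 and lung shRenilla at 4.97 to 5.03. In shAsns-2 the lung-derived cells had more proliferation and mitosis genes (13 higher, 2 lower of 36, adjusted p = 5.74e-05, but adjusted p = 0.267 with an estimated correlation).

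The difference between sites taken label by label was chosen after the Asns levels were seen. For the libraries labelled shAsns-1 it took in 33 epithelial genes with a higher and 1 with a lower change in lung (median 0.99, adjusted p = 2.04e-14 and adjusted p = 0.0232 with an estimated correlation). In the inflammatory list 16 genes had a higher and 2 a lower change (median 0.95, adjusted p = 1.33e-06, but adjusted p = 0.121 with an estimated correlation).

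The counts of called genes were set against other splits of the same libraries, in fits of the compared groups alone, so the splits bear on the counts of those fits. The labels do not say whether replicates are separate mice, cultures or preparations. The splits therefore bear only on how these libraries were grouped. They cannot exclude a chance difference between single mice or cultures. With 35 splits the lowest possible share giving as many genes is 1 of 35, unadjusted over the comparisons. That share was reached for tumor libraries labelled shAsns-1 against shRenilla (5120 genes, highest other split 0) and the hairpins in tumor (3699, other 0). It was also reached for lung against tumor in shRenilla (1869, other 0), in the libraries labelled shAsns-1 (3683, other 24) and in shAsns-2 (1650, other 30). For tumor shAsns-2 (3, other 0) and lung libraries labelled shAsns-1 (1, other 0) it was reached only for the few genes of these smaller fits. This says nothing on the other genes among the 8 and 26 called with all 24 libraries. For both hairpins in tumor (3, other 0, 1 of 100) the splits mixed all 3 labels. As the libraries labelled shAsns-1 differed in many genes, such splits cannot say whether the overlap of the hairpins is chance. With all 24 libraries 3 genes were higher in both (0.808 expected) and 2 lower in both (0.532 expected). That expectation leaves out the shared shRenilla libraries.

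For lung shAsns-2 (0 genes, as in 35 of 35 splits) and both hairpins in lung (0, as in 100 of 100) the splits say nothing about chance, because every split reaches a count of 0. EdgeR called 0 genes there with all 24 libraries as well. At an unadjusted p under 0.05 there were 1068 and 463 genes, DESeq2 called 2 and 1, and limma with library weights 1582 and 202. Chance was not excluded for the hairpins in lung, where the real split gave 6 genes, 2 of 35 splits gave as many, and the highest other gave 248. For the difference between sites, 2 of 100 splits gave as many as the real 317, and the highest other gave 764. These splits shuffled the hairpin labels within each site. Tumor libraries labelled shAsns-1 already differed from tumor shRenilla in 4278 genes, so the splits cannot decide on chance for a difference between sites. Splits that call 248 or 764 genes point to a structure of the samples. What it is was not tested.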
